A study of Homo sapiens with 6 samples.

How the data were processed

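RNA was measured by sequencing in LX-2 cells, a human line derived from hepatic stellate cells, the liver cells that lay down scar matrix when activated. Per the labels' protocols, the cells received a control small interfering RNA (siCTL) or an siRNA against ADAMTS12 (siADAMTS12) by lipid transfection for 48 h. Total RNA was extracted with TRIzol, RNA integrity numbers lay between 9.2 and 9.9, and stranded poly(A) libraries were made from 500 ng of RNA with fragments of about 260 bp. The 3 libraries of each group carry the replicate numbers 1 to 3. Nothing in the labels says that these came from separate cultures, so p-values measure the spread between these libraries, which can be partly technical.

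The submitters' processing notes name STAR, HTSeq, DESeq2 and the genome build GRCh38, without versions, and the gene annotation and strand setting are not given in the sources used here. The deposited values are a score rather than raw counts: the authors' table holds normalized counts, per the name of the file, as whole numbers. Median-of-ratios factors computed from the 6 deposited columns lay between 1.003 and 1.007, so the columns were already scaled to each other. In the columns of siCTL replicate 3 and siADAMTS12 replicate 2, 9 and 12 of the whole numbers from 1 to 40 were taken by no gene, as when counts are scaled up and their decimals dropped. A search for the spacing of such gaps and excesses gave implied totals (M, 1e6) of 45.6 M reads for siCTL replicate 2, 25.8 M for siCTL replicate 3, and 33.8, 21.8 and 42.5 M for siADAMTS12 replicates 1, 2 and 3. The spacing of siCTL replicate 1 was not resolved. Its best match correlated at 0.158 with the spacing of its values, against 0.137 in a simulated column without scaling. The search left out factors near 1, so a column scaled very little cannot be resolved by it. Whole reads were not rebuilt, because dropping decimals merged neighbouring counts in the columns scaled down, and no count model was fitted.

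Genes with a mean normalized count of at least 10 over the 6 libraries were kept, 15637 of 60669. The values were analysed as log2(value + 1), so the fold changes of low genes are understated. limma 3.58.1 in R 4.3.3 was fitted to all 6 libraries with group as the only term (lmFit, then eBayes with an intensity trend), and 2-sided p-values were adjusted by the Benjamini-Hochberg method over the genes kept, with a threshold of 0.05. Fold changes are siADAMTS12 over siCTL, with the moderated standard error (SE). Before the data were examined, 34 gene lists were fixed. Of these, 32 had at least 5 genes kept and were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera under an estimated correlation and fry beside it. The named genes follow a rule fixed at the same time. It takes ADAMTS12 and the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 50, a gene symbol that is not a clone name, and groups that do not overlap. From each list called by camera it takes up to 4 members, and from each other list up to 3, with the smallest adjusted p among members past the threshold, or the member with the smallest p where none passed. Some of the genes this rule takes are not reported here.

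Same-numbered libraries deviated together from their group means: the correlations of their deviations across genes were 0.37, 0.13 and 0.13 for replicates 1, 2 and 3, against -0.19 to 0.06 for libraries with different numbers. This met the rule set for this check (every pair above 0.1), and a fit with the replicate number as a block was run beside the fit without it. Deviations from a group mean cancel within the group, so the correlation for replicate 1 alone raises those among replicates 2 and 3. These stood at 0.13 for the same number against 0.06 for different numbers. The pairing therefore rests mainly on replicate 1.

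The siRNA's sequence, from the labels, was matched to GENCODE 29 transcripts on GRCh38. One transcript per protein-coding gene was taken by its APPRIS principal tag, then membership of the basic set, then the length of the 3' UTR. Its 3' UTR, of at least 30 bases, was searched for the sequence complementary to guide positions 2 to 8, which direct microRNA-like silencing, in 12609 kept genes. The mean log2 fold change of genes with and without each of 16189 7-mers was compared, as measured and after cubic trends over 3' UTR length, 3' UTR GC content and mean expression were taken out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and plots were made with matplotlib 3.10.9. The fit was tested on simulated data. In 10 draws of truncated, scaled counts for 15584 genes with 200 genes changed, it called 76.1% of genes changed by a log2 value of 0.5, 94.8% at 1 and 100% at 2, with 4.02% false calls. Camera called the changed list in 10 of 10 draws and none of 31 unchanged lists per draw. All members of the changed list fell, by log2 values of 0.5, 1 or 2. Its calls therefore do not show how often lists with smaller or mixed changes would be called. The simulated genes varied independently of each other, so these draws do not test false calls in lists whose members vary together. In the 7-mer search, 5 of 5 planted 7-mers with a shift of -0.1 ranked first in shuffled fold changes. Shuffling removes trends over the 3' UTR, so this check does not cover data that hold such trends. Alternatives covered the pseudocount, the filter on low values, 2 other scalings, the variance trend, the replicate block, each library left out, a stricter threshold and the list tests. No library, and no column of the deposited table, was left out of the analysis.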

Results

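The comparison asks how depletion of ADAMTS12, a secreted metalloprotease that cuts extracellular matrix proteins, alters gene expression in LX-2 cells. Poly(A) RNA was sequenced from 3 libraries of cells given siCTL and 3 given siADAMTS12, all collected 48 h after transfection. The deposited normalized counts summed to 33.75 ± 0.276 M (1e6) per siCTL library and 30.97 ± 0.393 M per siADAMTS12 library (SD, n = 3; exact 2-sided permutation p = 0.1, the smallest that 3 against 3 allows). These sums follow the scaling. The reads implied by the spacing of low values ranged from 21.8 to 45.6 M in 5 libraries and were not resolved in siCTL replicate 1. Log2 values correlated across genes at 0.991 to 0.994 within groups and at 0.985 to 0.988 between groups. Levels are normalized counts as mean ± SD over 3 libraries. Fold changes are on the log2(value + 1) scale, and adjusted p-values are from limma unless another test is named.

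ADAMTS12 (ENSG00000151388, chromosome 5, 33523535 to 33892192, minus strand, GRCh38) was the target. Its level was 13709, 12235 and 13423 in siCTL replicates 1, 2 and 3, and 4083, 3449 and 3687 in the siADAMTS12 replicates. The mean went from 13122 ± 782 to 3740 ± 320, a log2 fold change of -1.81 ± 0.07 (SE) that left 28.5% of the transcript (adjusted p = 4.81e-08; exact 2-sided permutation p = 0.1). The 19-base sense sequence GCCAAAGTTTGGAGGGAAA lies at chromosome 5, 33637728 to 33637746, on the minus strand, within the coding part of exon 12 in both protein-coding transcripts in which it was found. Among the genes that fell, ADAMTS12 ranked 21 by fold.

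With siADAMTS12, genes for integrins and focal adhesions, matrix proteases and their inhibitors, the endoplasmic reticulum folding machinery, fibrillar collagen processing and hypoxia-linked metabolism were lower as groups. Camera adjusted p ran from 2.40e-08 to 0.000308 for these 5 lists with its preset correlation, and none passed with an estimated one (adjusted p = 0.0694 to 0.239). Among the largest falls were the lysosomal membrane protein LAMP1 (6.40-fold) and the collagen-binding integrin subunit ITGA2 (4.09-fold). Among the largest rises were GFPT1, the rate-limiting enzyme of the hexosamine pathway (2.95-fold), and the serine transporter SFXN1 (2.92-fold). In all, 1798 genes rose and 2424 fell of 15637 tested, and 102 rose and 255 fell at least 2-fold. The groups did not overlap in 40.9% of the genes tested, where chance gives 10%.

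Among the genes that the naming rule admits, with a mean of at least 50, the 8 largest falls were RPL36AL, TCEAL3, LAMP1, TCEAL4, LINC00707, DOHH, RGS4 and ITGA2. Their log2 fold changes ran from -2.96 to -2.03. LAMP1 went from 14263 ± 773 to 2229 ± 152 (log2 fold change -2.68 ± 0.07 SE, adjusted p = 3.94e-09). RGS4, which shortens signalling through G proteins, went from 7911 ± 353 to 1764 ± 42.0 (-2.16 ± 0.06, adjusted p = 4.24e-09). DOHH, the hydroxylase that completes hypusine on eIF5A, went from 758 ± 85.7 to 151 ± 28.0. RPL36AL (5255 ± 564 to 674 ± 41.4), TCEAL3 (2015 ± 379 to 285 ± 33.9) and TCEAL4 (2275 ± 260 to 411 ± 18.5) have near-identical relatives, so their values are uncertain where the counting could split reads. The long non-coding RNA LINC00707 went from 276 ± 44.5 to 52.0 ± 6.56. Among the 8 largest rises under the same rule were INAVA, EMC10, RBM38, TMEM150A, GFPT1, SFXN1 and HIPK1, with log2 fold changes from 1.54 to 1.77. EMC10, a subunit of the complex that inserts membrane proteins in the endoplasmic reticulum, went from 1465 ± 71.5 to 4951 ± 215 (1.76 ± 0.06, adjusted p = 2.27e-08). The RNA-binding protein RBM38 went from 394 ± 6.43 to 1239 ± 34.6, and the kinase HIPK1 from 1427 ± 106 to 4135 ± 110.

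**Figure D1:**
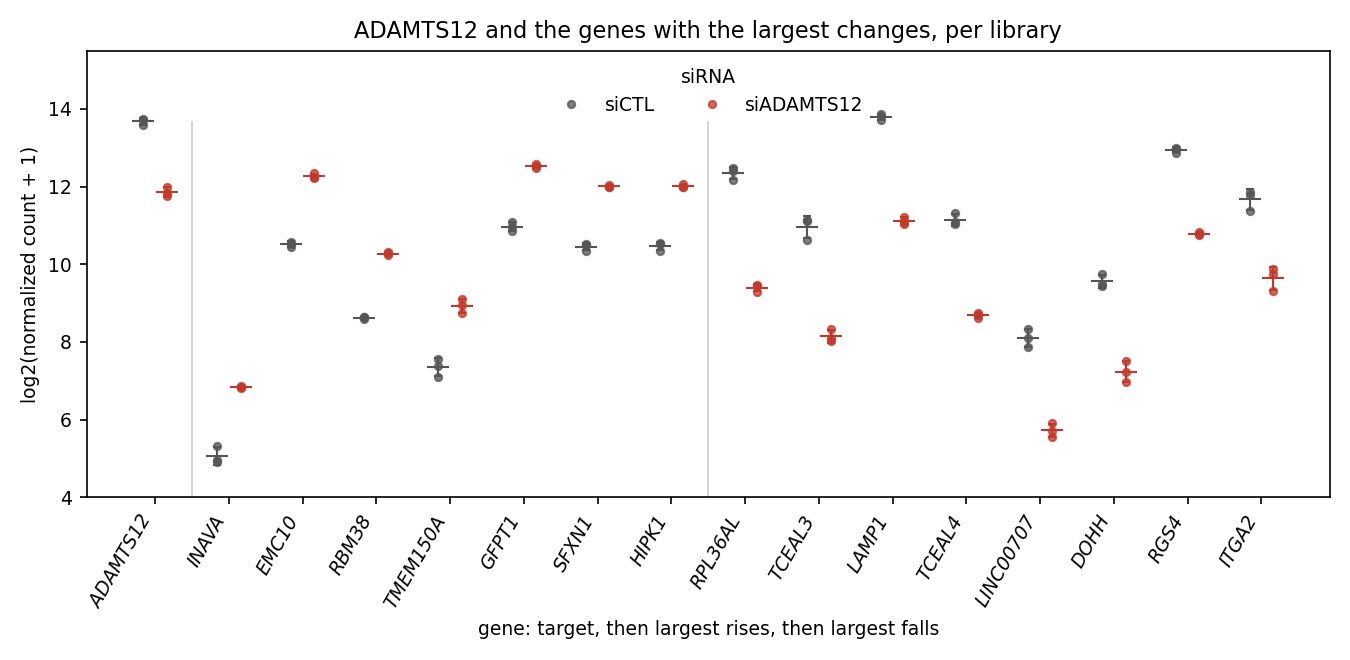
Level of ADAMTS12 and of 7 of the 8 genes with the largest rises and the 8 with the largest falls under the naming rule (x axis) as log2(normalized count + 1) (y axis), one point per library, with siCTL in grey, siADAMTS12 in red, and bars for the mean ± SD of 3 libraries. The 3 siADAMTS12 points lie outside the 3 siCTL points for every gene shown, with ADAMTS12 at a mean of 13122 in siCTL and 3740 in siADAMTS12.

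The 3' UTRs of the changed genes differed in how often they matched the siRNA guide. GAGGGAA, the match to guide positions 2 to 8, was in the 3' UTR of 15.6% of the 12609 genes searched, in 30.7% of those that fell, in 54.0% of those that fell at least 2-fold and in 10.9% of those that rose. Among the named falls, RPL36AL, LAMP1, DOHH and RGS4 carried it, while TCEAL3, TCEAL4 and ITGA2 did not and LINC00707 was not searched. EMC10 was the only one of the 7 named rises with this 7-mer. RBM38 and GFPT1 among the rises and ITGA2 among the falls held a 6-mer match, to guide positions 2 to 7, as did ADAMTS12. Among list genes named below, CAV1, ITGB3, ITGA3, ADAMTS1, THBS1, MYLK, PLOD1, LAMA4, HSPG2, TGFBR2, FZD4, PDGFRB and ICAM1 held the 6-mer without the 7-mer. The same was true of BIRC3, IL11, PDIA3, HMGCS1, IDI1, ATF4, SLC2A3, CDCA8, TUBB4B, PLK2, TP53INP1, SCARB2 and KLF6. Others, such as MMP9, TLL1, TNC, CALD1, VIM, AXL and CALR, held neither. LUM, ADAMTSL1, ADAMTSL3, FGF2, CSF1, NGFR, ROR1 and NUPR1, named below, also carried the 7-mer. So did SLC1A4, HSP90B1, TPI1, INSIG1, CDCA2, IRF1, TNRC6A, COL1A1 and COL1A2, while WT1 and MT-ND1 were not searched. The mean log2 fold change was 0.03 in 7397 genes with no match to the seed, -0.02 with a 6-mer match, -0.10 and -0.14 with either kind of 7-mer match, and -0.33 in 775 genes with the 8-mer GAGGGAAA, of which 47.5% fell.

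**Figure D2:**
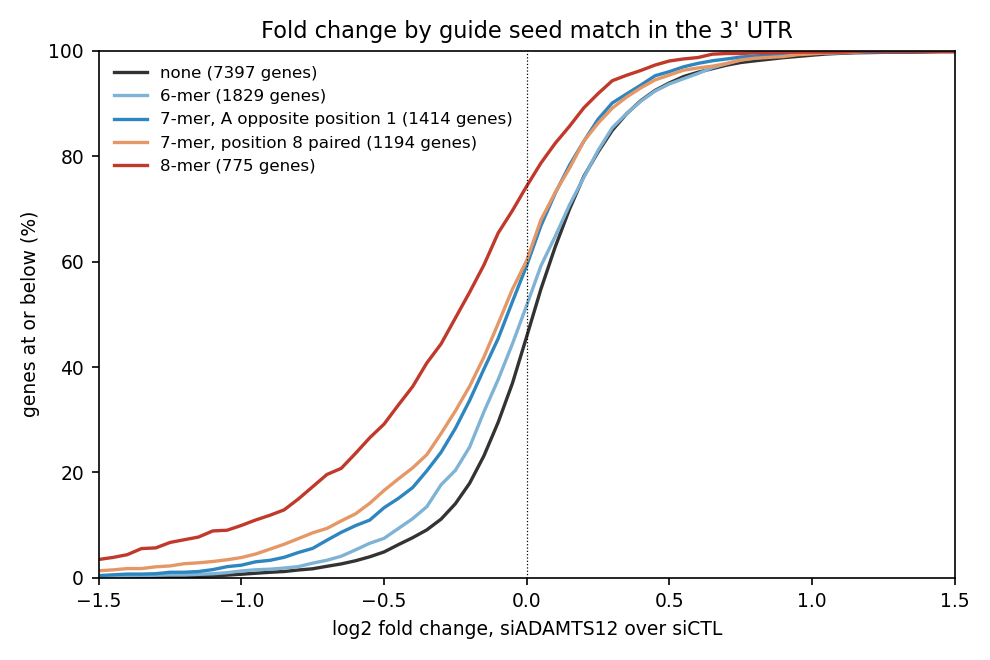
Cumulative share of genes (y axis, percent) at or below each log2 fold change of siADAMTS12 over siCTL (x axis), one line per class of guide seed match in the 3' UTR. The curve for genes with the 8-mer lies furthest to the left (mean -0.33), and the curve for genes without a match has a mean of 0.03.

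Matrix remodelling and adhesion genes were lower. Of 31 integrin and focal adhesion genes, 19 fell and 0 rose (20 fell adjusted over the list alone), with camera adjusted p = 2.40e-08 and adjusted p = 0.0694 with an estimated correlation. ITGA2 was among them, as were the caveolar protein CAV1 (25038 ± 1419 to 13365 ± 510), ITGB3 and ITGA3 (log2 fold changes -0.79 and -0.71). Of 32 matrix proteases and inhibitors, 19 fell and 0 rose (20 fell adjusted over the list alone), with camera adjusted p = 5.42e-08 and adjusted p = 0.168 with an estimated correlation. They included the plasminogen activator PLAT (9497 ± 488 to 3208 ± 190), its inhibitor SERPINE2 (8630 ± 745 to 2620 ± 198), and the gelatinase MMP9 (215 ± 1.00 to 58.7 ± 13.9). The guide 7-mer was in 6 of these 19 lower protease and inhibitor genes, PLAT and SERPINE2 included, and in 4 of the 19 lower adhesion genes. ITGA2, CAV1, ITGB3 and ITGA3 lacked the 7-mer but held the 6-mer match. In the ADAMTS family, 10 of 19 genes fell and 0 rose (11 fell and 1 rose adjusted over the list alone), with ADAMTS1 from 11579 ± 912 to 5351 ± 761 and with ADAMTSL1 and ADAMTSL3 at log2 fold changes of -0.92 and -1.15. Its camera adjusted p was 0.000652, with adjusted p = 0.216 with an estimated correlation, and it was 0.00284 with ADAMTS12, a member, left out.

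Of 27 fibrillar collagen and crosslinking genes, 13 fell and 1 rose (13 and 1 adjusted over the list alone). COL12A1 went from 19424 ± 819 to 10630 ± 1518, COL5A3 from 196 ± 13.7 to 88.3 ± 12.3, the procollagen-processing protease TLL1 from 1159 ± 75.6 to 614 ± 45.2, and the lysyl hydroxylase PLOD1 from 8717 ± 288 to 5896 ± 341. The list had camera adjusted p = 9.05e-05 and adjusted p = 0.239 with an estimated correlation, and 6 of its 13 lower members carried the guide 7-mer, COL12A1 and COL5A3 among them. Of 34 matrix glycoproteins and proteoglycans, 15 fell and 2 rose (16 and 2 adjusted over the list alone), with camera adjusted p = 0.000431 and adjusted p = 0.239 with an estimated correlation. THBS1 went from 20490 ± 1104 to 10594 ± 861, TNC from 44753 ± 1710 to 26755 ± 1084 and the small proteoglycan LUM from 67.3 ± 16.0 to 8 ± 0, whereas the cartilage matrix protein MATN3 rose from 275 ± 8.5 to 567 ± 22.6. Of 24 myofibroblast and contractile genes, 13 fell and 1 rose (13 and 1 adjusted over the list alone), with MYLK, CALD1 and VIM at log2 fold changes of -0.55, -0.60 and -0.55 and with CNN2 at 0.82. The myofibroblast list had camera adjusted p = 0.000431, adjusted p = 0.409 with an estimated correlation, and adjusted p = 0.265 after quantile normalization, with alternatives from 9.01e-06 to 0.409. VIM no longer passed there either (log2 fold change -0.26, adjusted p = 0.0564, the highest of its alternatives, from 0.000212). Of 23 basement membrane genes, 5 fell and 2 rose (6 and 2 adjusted over the list alone), with NID2 from 592 ± 99.8 to 1546 ± 284, HSPG2 at a log2 fold change of 0.37 and LAMA4 at -0.72, and the list did not pass (camera adjusted p = 0.420).

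**Figure D3:**
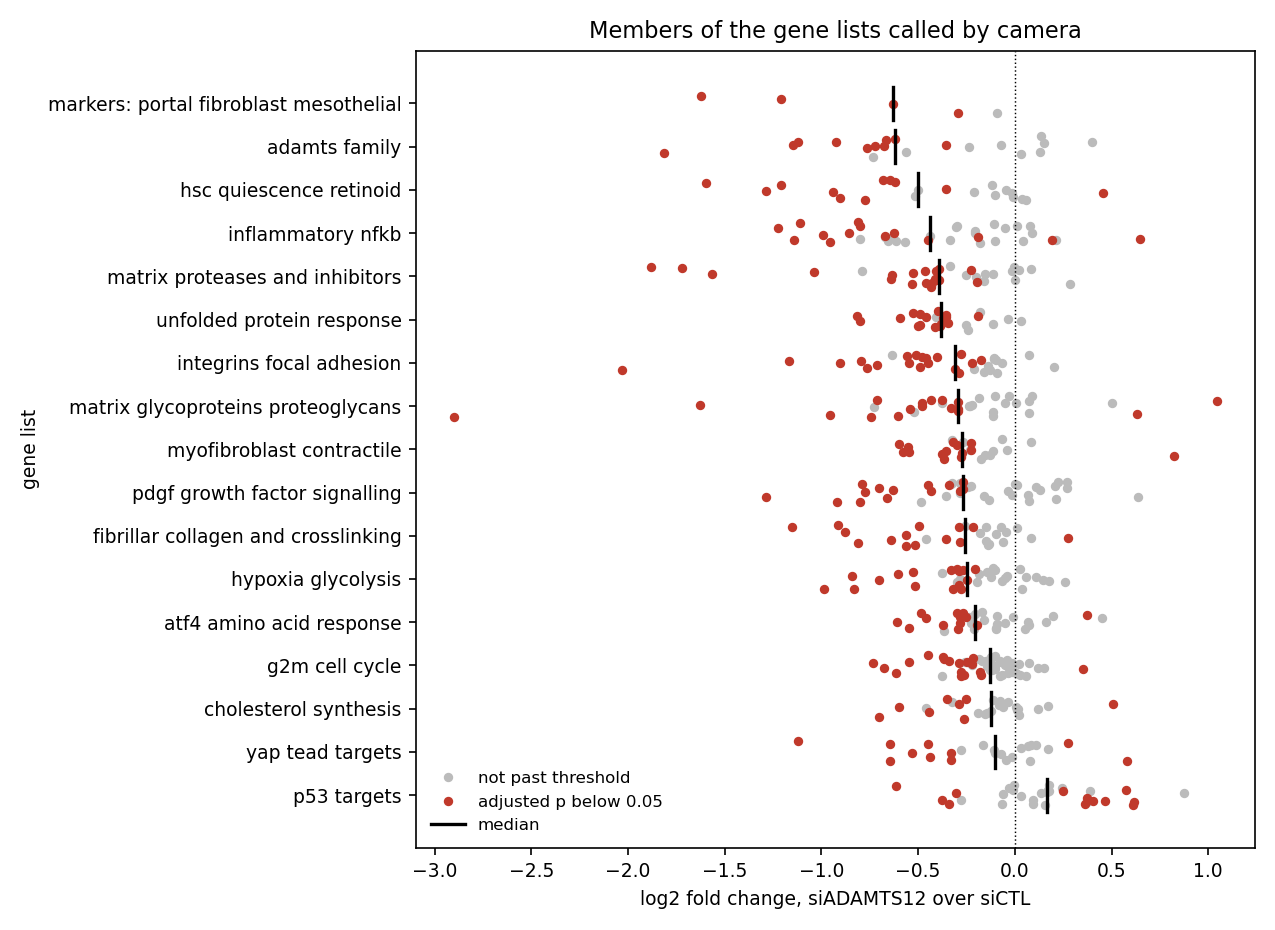
Log2 fold change of siADAMTS12 over siCTL (x axis) for each kept member of the 17 gene lists called by camera with its preset correlation (y axis), with members past adjusted p of 0.05 in red, the others in grey, and a bar at the list's median. The medians run from -0.63 for 5 portal fibroblast and mesothelial markers to 0.17 for 32 p53 targets, the 1 list of the 17 that was higher.

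Genes for protein folding and stress responses of the secretory pathway were lower. Of 24 unfolded protein response genes, 17 fell and 0 rose (19 fell adjusted over the list alone). They included the abundant chaperones PDIA3 (35798 ± 2379 to 20532 ± 722), HSP90B1 (37623 ± 3682 to 21339 ± 1214) and CALR (49529 ± 1847 to 35060 ± 1923) and the chaperone HYOU1 (log2 fold change -0.53). The list had camera adjusted p = 7.14e-08 and adjusted p = 0.239 with an estimated correlation, and 2 of the 17 lower genes carried the guide 7-mer. Of 33 genes of the ATF4 amino acid response, 12 fell and 1 rose (12 and 1 adjusted over the list alone), with camera adjusted p = 0.00278 and adjusted p = 0.392 with an estimated correlation. ATF4 itself was at -0.30 (-0.13 after quantile normalization, adjusted p = 0.138, with alternatives from 0.000972), the alanyl-tRNA synthetase AARS1 at -0.49, the amino acid transporter SLC1A4 at -0.55 and NUPR1 at -0.61. Of 35 hypoxia and glycolysis genes, 16 fell and 0 rose (16 fell adjusted over the list alone), with the peptide hormone ADM from 2886 ± 285 to 1454 ± 98.6, NDRG1 from 1569 ± 92.0 to 876 ± 67.4, the glycolytic enzyme TPI1 from 31276 ± 1761 to 19254 ± 1463 and the glucose transporter SLC2A3 at -0.53. The hypoxia list had camera adjusted p = 0.000308 and adjusted p = 0.239 with an estimated correlation. Of 25 cholesterol synthesis genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone), with HMGCS1, INSIG1 and IDI1 at -0.70, -0.44 and -0.35. The cholesterol list had camera adjusted p = 0.0324 and adjusted p = 0.639 with an estimated correlation. It did not pass without siCTL replicate 1 (0.0617), without siCTL replicate 2 (0.104) or without siADAMTS12 replicate 3 (0.170), nor after quantile normalization (0.199) or with a minimum mean of 50 (0.0664). Its alternatives ran from 0.00375 to 0.639.

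Growth factor and inflammatory genes were also lower. Of 38 genes of growth factor signalling, 14 fell and 0 rose (16 fell and 1 rose adjusted over the list alone), with camera adjusted p = 0.00275 and adjusted p = 0.239 with an estimated correlation. The receptor PDGFRB went from 1452 ± 187 to 830 ± 75, the ligand PDGFA from 781 ± 43.1 to 459 ± 58.7, and FGF2 and IGFBP4 were at log2 fold changes of -0.79 and -0.66. Of 35 inflammatory genes linked to NF-kappaB, 12 fell and 2 rose (14 and 2 adjusted over the list alone), among them CSF1 (4370 ± 207 to 2251 ± 50.2), ICAM1 (3965 ± 320 to 2273 ± 92.3), BIRC3 (-0.62) and the cytokine IL11 (1067 ± 61.2 to 491 ± 104). The inflammatory list had camera adjusted p = 0.000994 and adjusted p = 0.409 with an estimated correlation. Of 21 genes tied to stellate cell quiescence and retinoid storage, 10 fell and 1 rose (11 and 1 adjusted over the list alone), with NGFR, WT1, ADIPOR1 and IGFBP3 at -1.60, -1.21, -0.90 and -0.65 (camera adjusted p = 0.000734; adjusted p = 0.216 with an estimated correlation). Of 23 YAP and TEAD targets, 8 fell and 2 rose (9 and 2 adjusted over the list alone), with ROR1, NT5E and AXL at -1.12, -0.64 and -0.53. That list lay close to the threshold (camera adjusted p = 0.0494; adjusted p = 0.239 with an estimated correlation) and did not pass without siCTL replicate 2 (0.0844), siCTL replicate 3 (0.0608) or siADAMTS12 replicate 1 (0.105), after quantile normalization (0.573), with a pseudocount of 8 (0.0517) or with a minimum mean of 50 (0.0959). Its alternatives ran from 0.0039 to 0.573.

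Cell cycle genes moved in part. Of 53 genes of the G2 and M phases, 17 fell and 1 rose (18 and 1 adjusted over the list alone), with CDCA2, CDCA8, TUBB4B and ANLN at log2 fold changes of -0.73, -0.68, -0.55 and -0.45. The list had camera adjusted p = 0.000397, adjusted p = 0.574 with an estimated correlation and adjusted p = 0.103 after quantile normalization, with alternatives from 5.79e-07 to 0.574. Of 50 genes of the G1 to S transition, 10 fell and 6 rose (12 and 6 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.583). Cyclin E1 (CCNE1) rose from 384 ± 15.7 to 905 ± 44.0 and the flap endonuclease FEN1 from 3521 ± 120 to 6914 ± 459. Of 32 p53 targets, 8 rose and 4 fell (11 and 5 adjusted over the list alone), with the cell cycle inhibitor CDKN1A (1558 ± 127 to 2396 ± 255), TP53INP1 and SESN1 among the rises and the kinase PLK2 (12169 ± 106 to 7947 ± 231) among the falls. The p53 list had camera adjusted p = 0.0306 and adjusted p = 0.574 with an estimated correlation, and did not pass without siCTL replicate 3 (0.0757) or siADAMTS12 replicate 1 (0.0725), with alternatives from 0.00917 to 0.574.

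Several lists did not pass camera. Of 31 TGF-beta targets, 7 fell and 3 rose (8 and 5 adjusted over the list alone; camera adjusted p = 0.209), with the receptor TGFBR2 from 8177 ± 438 to 4216 ± 283. Of 19 Wnt genes, 5 fell and 2 rose (5 and 2 adjusted over the list alone; 0.186), with WNT5B, FZD4 and DKK3 at -0.79, -0.74 and -0.51. Of 24 NRF2 targets, 5 fell and 1 rose (5 and 1 adjusted over the list alone; 0.136): the quinone reductase NQO1 went from 3140 ± 347 to 906 ± 145 and GCLM from 2216 ± 80.5 to 761 ± 116, both with a guide 7-mer in the 3' UTR, while TALDO1 rose from 1608 ± 60.2 to 3051 ± 104. Of 35 lysosome and autophagy genes, 11 fell and 4 rose (11 and 4 adjusted over the list alone; 0.165), with SCARB2 and SQSTM1 at -0.54 and -0.50 beside LAMP1. Of 37 interferon genes, 3 fell and 0 rose (2 and 0 adjusted over the list alone), with IRF1 at -0.46, and the list's camera adjusted p of 0.420 became 0.00229 without siADAMTS12 replicate 2 (alternatives from 0.00229 to 0.967). Of 13 mitochondrially encoded genes, 1 fell (1 adjusted over the list alone), MT-ND1 at -0.79, and the list's camera adjusted p of 0.278 became 0.0280 without siCTL replicate 1 and 0.0336 without siADAMTS12 replicate 2 (alternatives from 0.0280 to 0.932). Of 53 ribosomal protein genes, 2 fell and 1 rose (0 and 0 adjusted over the list alone), with camera adjusted p = 0.297, but after quantile normalization the list was higher (camera adjusted p = 7.67e-07, mean log2 fold change 0.20; alternatives from 3.99e-07 to 0.887). Of 24 fatty acid synthesis and storage genes 4 fell and 1 rose, of 39 nuclear oxidative phosphorylation genes 4 fell and 4 rose, and of 22 immediate early genes 3 fell and 2 rose, with the same numbers adjusted over the list alone and camera adjusted p of 0.583, 0.612 and 0.420. PLIN3 was at -0.47, NDUFB10 at -1.03, NDUFA1 at 0.63 and KLF6 at -0.57 in these 3 lists. For oxidative phosphorylation, the median (0.02) and camera pointed up and the mean (-0.003) down. Of 13 genes of the RNA interference machinery, 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.309), with TNRC6C from 587 ± 59.5 to 1340 ± 175 and TNRC6A at -0.50.

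Markers of other liver cell types ranged from absent to abundant. Of 86 such genes, 24 had a mean of at least 10. Of 28 hepatocyte markers, 13 were at 0 in all 6 libraries and 4 were kept, the highest being CPS1 (1979 ± 47.5 to 2649 ± 248, log2 fold change 0.42). Of 18 leukocyte and Kupffer cell markers 3 were kept, none of them past the threshold (CSF1R at -0.43, adjusted p = 0.262). These lists were too short to test. None of 6 cholangiocyte and epithelial markers passed (KRT7 at -0.23, adjusted p = 0.106; camera adjusted p = 0.654), and KRT18, KRT8 and SOX9 were abundant in both groups, with means over the 6 libraries of 9691, 6638.5 and 1676.5. Of 6 endothelial markers, KDR and TIE1 fell (log2 fold changes -1.09 and -0.71; 2 adjusted over the list alone), with camera adjusted p = 0.130. Of 5 portal fibroblast and mesothelial markers, WT1, GREM1, THY1 and FBLN2 fell (-1.21, -1.62, -0.63 and -0.30; 4 adjusted over the list alone), with camera adjusted p = 0.00193 and adjusted p = 0.239 with an estimated correlation, and GREM1 and THY1 carried the guide 7-mer. FBLN2 did not pass after quantile normalization (-0.19, adjusted p = 0.0964), with no variance trend (0.0796), or without siCTL replicate 1 (0.0546), siCTL replicate 2 (0.0697) or siADAMTS12 replicate 3 (0.0758), with alternatives from 0.00102. WT1 is also a member of the quiescence list.

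Of the 32 lists tested, camera with its preset correlation called 17, 16 of them lower, whereas 0 were called with an estimated correlation, 5 having an unadjusted p below 0.05. Fry, which does not compare a list with the other genes, called 12 of the 17. It did not call the myofibroblast (fry adjusted p = 0.0544), inflammatory (0.0501), G2 and M phase (0.0796), p53 (0.148) and cholesterol (0.132) lists, and it called 4 lists lower that camera did not, the TGF-beta (0.00394), Wnt (0.0301), lysosome (0.0141) and endothelial (0.0033) lists. Median fold changes ran from 0.08 in the tenth of genes with the lowest means to -0.10 in the tenth with the highest. After quantile normalization, CALD1, AXL, TUBB4B, CALR and TPI1 still passed, at -0.36, -0.31, -0.33, -0.26 and -0.47. Lower members with the guide 7-mer numbered 4 of 10 in the ADAMTS list, 2 of 15 for glycoproteins and 3 of 13 for the myofibroblast list. They numbered 5 of 16 for hypoxia, 3 of 12 for ATF4, 3 of 14 for growth factors and 2 of 12 for inflammation. They numbered 2 of 10 for quiescence, 1 of 8 for YAP and TEAD, 1 of 17 for G2 and M and 1 of 7 for cholesterol.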

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

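The tests without the guide 7-mer, with trends taken out and limited to annotated genes were chosen after seeing the data. ADAMTS12 kept its direction and passed under every setting run, with log2 fold changes from -1.88 to -1.69. The number of genes changed stayed within 1.5 times of 4222 under the other pseudocounts, filters, scalings and variance model (3345 to 4253) and with one library left out (3102 to 3987). It was 2487 at an adjusted p below 0.01, a stricter threshold by construction. With the replicate block, which pairs the libraries, it was 5482, including 4219 of the 4222. ADAMTS12 stayed at -1.81, 383 genes changed at least 2-fold and 17 lists were called, the same 17, and the block changed no call among the other genes the rule takes. Genes changed at least 2-fold numbered 357, between 253 and 445 under the other planned settings and 324 to 382 with one library left out, but 172 among the 10640 genes whose searched 3' UTR lacks the guide 7-mer, against 303 among all 12609 genes searched. Lists called numbered 17, between 14 and 17 across pseudocounts, filters and scalings, 15 to 19 with one library left out, 16 with fry, and 0 with an estimated correlation. The cause of that last loss was not tested. In the integrin list (-0.0023) and the YAP and TEAD list (0.0033) the estimated correlation lay below the preset 0.01. A raised correlation therefore does not account for the loss of these lists, and the forms of camera differ in more than the correlation. Adjusted p-values with an estimated correlation thus do not measure correlation between members alone. In the other called lists the estimated correlation ran from 0.0187 to 0.405. Of the marker genes of other cell types, 59 of 86 had a value above 0 in any library, against 24 with a mean of at least 10, by construction of the filter. For the 119 other genes the rule takes, 1257 of 1266 values under other settings and 698 of 714 with one library left out kept their direction and side of the threshold, and the rest no longer passed. For the 32 lists these were 422 of 476 and 173 of 192; 39 and 8 values no longer passed, 6 and 3 newly passed, and 9 and 8 changed the test's direction without a call. Quantile normalization moved the median of all genes by 0.02 and the share of lower genes from 57.4% to 48.9%. Planned tests with edgeR and DESeq2 were not run, since whole reads could not be rebuilt. Fewer low genes passed: 71 of 1564 genes in the tenth with the lowest means changed, against 618 in the highest, at implied depths of 21.8 M to 45.6 M reads in 5 libraries and an unresolved depth in siCTL replicate 1.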

Other observations

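COL1A1 and COL1A2, the chains of type I collagen, went from 114287 ± 8085 to 100885 ± 8709 and from 9288 ± 1127 to 7772 ± 961 (SD, n = 3), log2 fold changes of -0.18 and -0.26 (limma adjusted p = 0.177 and 0.0907; 0.0259 and 0.00215 with the replicate block). COL3A1 was at -0.14 (adjusted p = 0.593; 0.0377 with the block), FN1 at -0.24 (0.157; 0.0340 with the block), and smooth muscle actin, ACTA2, at -0.15 (0.631; 0.0559 with the block). CCN2 and TGFB1 were at -0.10 and -0.13 and passed in neither fit. These 7 genes were chosen after their values were seen and stand for no list.

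The share of lower genes without a 6-mer match and the search for the most positive 7-mer were tests chosen after the result was seen. The checks of the gene lists without the guide 7-mer, with trends taken out or limited to annotated genes were added after seeing the data. Genes that fell carried the guide 7-mer in 706 of 2301 searched 3' UTRs, against 175 of 1600 genes that rose (30.7% and 10.9%). A candidate explanation is seed-matched off-target silencing by the guide strand: genes with the 7-mer differed by -0.21 from genes without it in mean log2 fold change, the most negative z (-23.1) of 16189 7-mers (permutation p = 1e-05, the smallest that 100000 permutations can give), and genes with 1, 2 and at least 3 sites averaged -0.19, -0.27 and -0.36. The tables argue against the passenger strand, whose 7-mer had a difference of -0.04 (z -4.85, permutation p = 1e-05, as for the guide) but ranked at 23.0% from the most negative and differed by 0.003 with the trends over 3' UTR and expression taken out, and against 3' UTR length, base composition and expression level, since the difference was -0.19 with those trends taken out. Direct silencing through the 3' UTRs searched does not cover the whole pattern. In these, 38.6% of the lower genes searched had no 6-mer match, against 7397 of all 12609 genes searched. Matches in other 3' UTRs of these genes stay open, since 1 transcript per gene was searched. The excess of lower genes with the 7-mer over the rate without it came to 17.9% of the lower genes searched. That rate includes genes with other guide matches, so 17.9% does not cap the share from direct silencing. Lower genes numbered 325 of 1829 with only a 6-mer match and 381 of 1414 with the 7-mer ending in an A opposite position 1. With no match they numbered 889 of 7397. For the rest of the pattern, loss of ADAMTS12 and indirect effects of seed-matched genes stay open and untested, since 1 siRNA against ADAMTS12 was used.

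The 16 lists called lower, from integrins to the unfolded protein response, may follow the guide's direct matches or trends across genes. Among genes with a searched 3' UTR and no guide 7-mer, 15 of the 16 were called lower, against 13 among all genes with a searched 3' UTR and a median of 13 (11 to 15) in 50 random draws of as many of them, and the portal fibroblast list had too few searched members to test in any of these. With the trend over expression level taken out 12 stayed called, the myofibroblast, YAP and TEAD, G2 and M phase and cholesterol lists no longer passing, and with the trend over GC content and transcript length taken out, among the 12787 genes with both values, 14 did, as did 14 among those genes with no trend taken out, in each case without the YAP and TEAD and cholesterol lists. The genes left without the guide 7-mer still included 1829 with a 6-mer match and 1414 with the 7-mer ending in an A opposite position 1. The first check therefore covers GAGGGAA only and leaves these other guide matches open. Without the 7-mer genes, mean log2 fold changes shrank from -0.45 to -0.35 for proteases and from -0.48 to -0.35 for quiescence. For integrins the mean stayed at -0.42. Camera compares a list with the other genes, whose mean rises when 7-mer genes (mean -0.21) leave. The YAP and TEAD list was called (camera adjusted p = 0.0447) at a mean of -0.14, from -0.17. Counts of calls without the 7-mer therefore do not settle the question alone. Within these limits, the means left argue against the guide 7-mer, and the calls against each trend, as the whole cause. The 7-mer as part of the cause stays open. For the portal fibroblast list the guide 7-mer stays open as the whole cause too (mean log2 fold change -0.77, and -0.19 in the 2 members searched and without the 7-mer). The expression trend stays open for the myofibroblast, G2 and M phase, YAP and TEAD and cholesterol lists, whose calls ended as their mean log2 fold changes shrank from -0.23, -0.16, -0.17 and -0.15 (SD over members 0.28, 0.20, 0.36 and 0.26) to -0.05, -0.07, -0.06 and -0.09 (SD 0.29, 0.21, 0.36 and 0.25). Limiting the genes alone ended the YAP and TEAD and cholesterol calls at unchanged means (adjusted p = 0.101 and 0.0726), so those 2 losses are not put down to the GC and length trend (means -0.12 and -0.13, SD 0.34 and 0.24, with it out). Depletion of ADAMTS12, the biological difference in the design, and indirect effects of off-target genes stay open as untested hypotheses.

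Across all genes searched, the 7-mer GTAGCGC had the most positive shift, with 47 of 109 genes that carry it in the 3' UTR higher and 9 lower. A candidate explanation is silencing by the control siRNA in the control libraries, which would appear as a rise with siADAMTS12. With the trends taken out its z was 9.83, against 7.90 for the next 7-mer that does not overlap it, GTAGTGC, which differs by C5T (positions from the 5' end), and 4.80 for the highest of 385 7-mers with the same bases in another order. The sequence of the control siRNA is not in the sources used here, so silencing by the control siRNA cannot be told apart from regulation tied to this 7-mer. Of the genes at least 2-fold higher whose 3' UTR was searched, 7 of 77 carried it (9.09%, against 0.864% of all genes searched; odds ratio 12.2, Fisher's exact p = 4.34e-06, 2-sided, across genes that are not independent). The 7-mer was picked for its shift in these same fold changes, so this enrichment is not separate support. The effect of ADAMTS12 depletion on the 2-fold higher genes without the 7-mer was not tested separately.

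Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes changed as the real split, that split itself (4222), the highest of the others giving 0, and 10 splits are too few for a share under 0.05.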
